A study of Homo sapiens with 24 samples.

How the data were processed

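RNA of HCC1806 and MDA-MB-231 populations was read by 3′ tag sequencing (TAGseq) after 48 hours of growth, per the labels' protocols. STAR and Salmon are named without versions, per the submitters' processing notes, with GRCh38 as the build. The annotation, trimming, strand setting and any removal of duplicates by molecular identifier are not recorded, so values of overlapping or antisense genes are uncertain. The deposited tables hold estimated counts per gene from Salmon and, as a separate deposited table, TPM with an equal sum in each library. The tables hold 29744 genes, 61 of them with a gene name held more than once, and 4.41% of the estimated counts were not whole. Every column was mapped to a labelled sample. The 24 libraries form 8 groups of 3 biological replicates: control, fusion, slippage and cytokinesis failure in each line. Choices of test, filters, gene lists, named genes and alternatives were fixed before the data were examined, except those stated as added later.

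Estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood F-tests), with each line fitted apart on its 12 libraries and 4 groups. Benjamini-Hochberg adjusted p below 0.05 defined a call. Standard errors were taken from the fold change and the F statistic, and need not match the p-values exactly. Contrasts were each doubled population against control, their mean against control, the doubled populations against each other, and the difference of the fold changes between lines in a fit of all 24 libraries. Lists of genes (34 lists, at least 5 tested members) and chromosome arms (at least 20 tested genes) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with the estimated correlation and fry beside it. Arms were assigned from RefSeq positions on GRCh38, which placed 24810 genes of the tables and 97.7% of the tested genes in either line. Symbols follow the tables, which hold some older ones. Named genes come from, for each doubled population against control, the 10 rising and 10 falling genes of largest fold change among called genes with a mean log2 CPM of at least 2 and 3 libraries of a group all above those of the other; the 10 and 10 of largest mean change called the same way in all 3 populations, and in both lines; up to 4 members of each list with the smallest adjusted p; 10 genes fixed in advance, among them KIF18A, CDKN1A, CCND2, PLK4, LATS2, MYC, CCNE1, CDKN2A and KIFC1; and 5 per direction for the line differences. Some genes and lists that this rule or the list tests cover are not reported here.

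The alternatives were DESeq2 1.42.0, RLE factors, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), no filter and a stricter filter, a minimum of 1 on the log2 scale, fits of the 6 libraries compared, leaving out each replicate, and a block for the replicate number. Added after the data were seen were leaving out both noisier libraries, list and arm tests in the pairs and line differences (also over genes tested in both lines), a correction of log2 CPM for GC content and transcript length, and thinning of libraries to the smallest total. The tests were run on data simulated from gene means and library sizes. For HCC1806 fusion against control (11467 genes), 51 of 100 genes changed by 0.5 on the log2 scale and 86 of 100 changed by 1 were recovered with 3 false calls (2.14%); for MDA-MB-231 fusion against control (11424 genes), 60 and 82 of 100 with 10 false calls (6.58%). A 0.15 shift of a list and an arm was recovered in both lines, with no gene correlation simulated. Standard errors rest on 3 replicates per group and cover counting error and variation between replicates of a population, not variation between independently derived populations. The low-pass genome sequencing that the study describes was not analysed.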

Results

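TAGseq, a 3′ tag-based RNA sequencing method that reads the ends of polyadenylated transcripts, was carried out on 24 libraries from HCC1806 and MDA-MB-231, both established lines of triple-negative breast cancer (TNBC, lacking oestrogen receptor, progesterone receptor and HER2). HCC1806 has basal epithelial features and MDA-MB-231 mesenchymal features. In each line, a parental aneuploid population, called the control here, was set beside 3 populations whose genome had doubled by cell fusion, by mitotic slippage (leaving mitosis without division) or by failed cytokinesis, and that had been sorted and expanded before sampling. Each of the 8 groups held 3 biological replicates. The design holds 1 derived population per route and line, so that route and population coincide in every comparison between routes. Totals of estimated counts per library ran from 3060622 to 4030297 in HCC1806, with 14701 to 15235 genes detected, and from 2455707 to 3837957 in MDA-MB-231, with 14141 to 14850 genes detected. The biological coefficient of variation between replicates was 3.88% in HCC1806 and 5.28% in MDA-MB-231. Fold changes are given on the log2 scale with their standard error after ±, and levels in TMM-scaled CPM as mean ± SD of 3 replicates; members of a list are those tested, and rose, fell or called refer to an adjusted p below 0.05. Kept at gives a list's camera adjusted p with an estimated correlation.

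In HCC1806, the first principal component (PC1, 21.6% of the variance) placed fusion at -16.2 to -14.7, control at -12 to -6.25, slippage at 2.92 to 5.98 and cytokinesis failure at 14.4 to 23.4. In MDA-MB-231, PC1 (26.0%) placed fusion at 24.9 to 28, and the other populations at -6.68 to -4.37 (control), -7.05 to -5.98 (slippage) and -15.2 to -13.3 (cytokinesis failure). Control and slippage overlapped there but lay apart on PC2 (11.5%), at 11.7 to 19.4 and -16.8 to -2.91. Replicate 3 of slippage and replicate 1 of cytokinesis failure in MDA-MB-231 stood apart, with chi-square per degree of freedom of 2.34 to 2.55 in their pairs against 1.29 to 1.92 in all other replicate pairs of both lines. The vimentin gene VIM, an intermediate filament abundant in MDA-MB-231, had at most 7 counts in any HCC1806 library (0.0646% of its MDA-MB-231 level), and the basal keratin KRT5 at most 1 count in MDA-MB-231 (0.0763% of its HCC1806 level). Of the immune cell markers, CD68 alone was tested. Their summed level in MDA-MB-231, mostly CD68, a lysosomal membrane protein, was 79.6 ± 4.31 CPM in control, 103 ± 9.65 in fusion, 117 ± 1.22 in slippage and 121 ± 7.34 in cytokinesis failure. Summed fibroblast markers in HCC1806 stood at 119 ± 10.3 CPM in control, 93.5 ± 3.27 in fusion, 133 ± 4.46 in slippage and 156 ± 8.30 in cytokinesis failure.

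**Figure D1:**
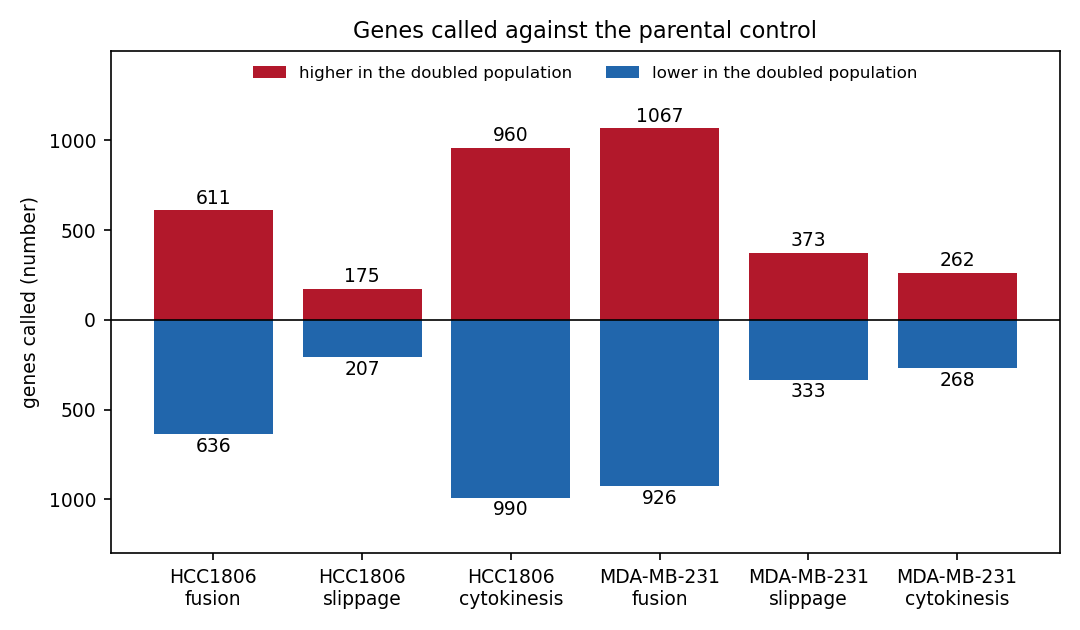
Genes called by edgeR in each doubled population against its control (bars above 0 higher, below 0 lower; y axis, number of genes), for example 960 higher and 990 lower after cytokinesis failure in HCC1806.

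Fusion-derived HCC1806 cells had lower DKK3, TNC and MAGEC2 transcripts and higher NEFH, CLDN8 and IGF2BP1 transcripts than control. DKK3, a secreted glycoprotein of the Dickkopf family (chromosome 11, 11963036 to 12009745 on GRCh38), fell by 3.65 ± 0.42. Its level was 0.588 ± 0.283 CPM in the fused cells and 7.76 ± 1.39 CPM in the controls. The matrix glycoprotein tenascin-C (TNC, -2.53 ± 0.36), the cancer-testis antigen MAGEC2 (-2.10 ± 0.27) and the microfibril protein MFAP5 (-1.70 ± 0.19) fell as well. NEFH, the neurofilament heavy chain (chromosome 22, 29480218 to 29491390 on GRCh38), rose most among the named genes, by 1.83 ± 0.21. Its level was 23 ± 4.58 CPM in the fused cells and 6.32 ± 1.46 CPM in the controls. The tight junction protein CLDN8 (1.60 ± 0.36), the RNA-binding protein IGF2BP1 (1.35 ± 0.20), the methyltransferase-like METTL7A (1.19 ± 0.28), the stem cell transcription factor SOX2 (1.02 ± 0.19), gamma-synuclein (SNCG, 1.00 ± 0.11) and the laminin receptor BCAM (0.93 ± 0.17) rose. The epithelial transcription factor ELF3 (0.77 ± 0.10) and the endoplasmic reticulum protein AGR2 (0.62 ± 0.072) rose, while the retinol dehydrogenase DHRS9 (-1.17 ± 0.18), the lipolysis inhibitor G0S2 (-1.24 ± 0.17) and the prostaglandin synthase PTGS2 (-1.11 ± 0.18) fell. The largest adjusted p among these genes was 0.00163. The cell cycle inhibitor CDKN1A fell by 0.65 ± 0.11 and cyclin E1 (CCNE1) by 0.49 ± 0.092. MYC fell by 0.27 ± 0.068 (adjusted p = 0.00365). The MYC call was lost without control replicate 2 (adjusted p = 0.0510). The mitotic kinesin KIF18A (0.17 ± 0.087), PLK4, LATS2 and KIFC1 were not called. edgeR called 1247 of 11467 genes (611 higher and 636 lower), 86 of them by at least 2-fold. DESeq2 called 648 genes, and limma on log2(TPM + 1) 234 higher and 472 lower.

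Among the gene lists, those of mitosis and of integrins held their call in fusion-derived HCC1806 under every correlation setting. In the mitosis and spindle list, 9 of 46 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00211, kept at 0.0370), led by the anaphase activator CDC20 (0.34 ± 0.048) and the checkpoint kinase BUB1 (0.34 ± 0.075). Of the integrins and cell-matrix adhesion genes, 3 of 28 rose and 12 fell (4 and 14 adjusted over the list alone; camera adjusted p = 3.20e-05, kept at 0.0370). Examples were thrombospondin THBS1 (-0.42 ± 0.045) and the laminin chain LAMB3 (-0.49 ± 0.051) among the lower ones. For nuclear-encoded oxidative phosphorylation, 29 of 72 rose and 1 fell (36 and 2 adjusted over the list alone; camera adjusted p = 4.25e-09, lost at adjusted p = 0.0788 with an estimated correlation). Examples were UQCRFS1 of complex III (0.49 ± 0.045) and NDUFB10 of complex I (0.35 ± 0.054). Cytosolic ribosomal proteins moved upward, where 53 of 76 rose and 1 fell (59 and 3 adjusted over the list alone; camera adjusted p = 2.31e-15, lost at adjusted p = 0.178 with an estimated correlation), RPS27 (0.32 ± 0.035) and RPL35 (0.32 ± 0.038) among them; such genes have many near-identical pseudogenes and are uncertain. Hippo pathway YAP and TAZ targets shifted downward, as 1 of 28 rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00635, lost at adjusted p = 0.0858 with an estimated correlation). Tissue factor F3 fell by 0.45 ± 0.037 and the YAP target ANKRD1 rose by 0.52 ± 0.085. Basal and squamous keratinocyte genes moved in both directions, and 4 of 30 rose and 8 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.0482, lost at adjusted p = 0.111 with an estimated correlation). The basal keratin KRT14 fell by 0.59 ± 0.064 and the suprabasal keratin KRT13 rose by 0.41 ± 0.046. Further lists moved downward, namely mesenchymal genes (0 rose and 5 fell of 20, 0 and 6 adjusted over the list alone; fibronectin FN1 at -1.26 ± 0.19 and N-cadherin CDH2 at -0.71 ± 0.11), TGF-beta targets (1 and 8 of 24, 2 and 9), immediate early genes (1 and 6 of 21, 1 and 10), ABC transporters and drug metabolism (1 and 7 of 24, 1 and 7; CYP1B1 at -0.79 ± 0.059) and fibroblast markers (0 and 2 of 5, 0 and 2; MFAP5 among them). Their camera adjusted p, from 0.00244 to 0.0493, became adjusted p from 0.0788 to 0.178 with an estimated correlation. Upward went cholesterol biosynthesis (4 rose and 0 fell of 25, 4 and 0 adjusted over the list alone) and glycolysis (5 and 2 of 20, 6 and 2; the isomerase GPI at 0.40 ± 0.041). The camera adjusted p of these, from 0.0254 to 0.0453, became adjusted p from 0.112 to 0.162 with an estimated correlation. The calls that 1 library decided were mesenchymal genes without control replicate 1, 2 or 3 or fusion replicate 2 or 3 (adjusted p from 0.0661 to 0.0822); keratinocyte genes without control replicate 1, 2 or 3 or fusion replicate 1 or 2 (adjusted p from 0.0531 to 0.0810); cholesterol biosynthesis without control replicate 2 (adjusted p = 0.15). Also lost were glycolysis without control replicate 1 or 3 or fusion replicate 2 or 3 (adjusted p from 0.0531 to 0.126); TGF-beta targets without control replicate 3 (adjusted p = 0.0677); drug metabolism without control replicate 1 or fusion replicate 2 (adjusted p from 0.0531 to 0.0545).

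Slippage-derived HCC1806 cells had lower BAIAP2L2, G0S2 and MMP1 and higher APOBEC3B, BCAM and SOX2 transcripts than control. BAIAP2L2, an adaptor with a BAR domain (chromosome 22, 38084900 to 38110967 on GRCh38), fell by 1.44 ± 0.22. Its level was 5.90 ± 2.72 CPM in the slippage cells and 16.2 ± 3.12 CPM in the controls. Lower transcripts also included G0S2 (-1.07 ± 0.17), the collagenase MMP1 (-0.99 ± 0.079), DHRS9 (-0.96 ± 0.18) and the urokinase PLAU (-0.75 ± 0.11). APOBEC3B, a cytidine deaminase acting on single-stranded DNA (chromosome 22, 38982347 to 38992779 on GRCh38), rose by 1.06 ± 0.25. Its level was 9.47 ± 1.32 CPM in the slippage cells and 4.52 ± 0.576 CPM in the controls. BCAM (0.96 ± 0.17), the transcription factor SOX2 (0.87 ± 0.19) and gamma-synuclein SNCG (0.75 ± 0.11) rose. The largest adjusted p among these genes was 0.00424. EGR1, an immediate early transcription factor, fell by 1.52 ± 0.29. The EGR1 call was lost on log2(TPM + 1) (adjusted p = 0.0534). CDKN1A fell by 0.63 ± 0.11 and MYC by 0.42 ± 0.070. CCNE1 fell by 0.34 ± 0.089. The CCNE1 call was lost without control replicate 1 or 2 or slippage replicate 1 or 2 (adjusted p from 0.0515 to 0.0837), with DESeq2 (adjusted p = 0.148) and on log2(TPM + 0.1) (adjusted p = 0.0524). The kinesin KIF18A, on which cells with doubled genomes have been reported to depend, rose by 0.30 ± 0.085 (adjusted p = 0.0324). The KIF18A call was lost without control replicate 1 or 2 or slippage replicate 1 (adjusted p from 0.0873 to 0.322), with DESeq2 (adjusted p = 0.25) and on log2(TPM + 1) (adjusted p = 0.310). PLK4, LATS2 and KIFC1 were not called. edgeR called 382 of 11467 genes (175 higher and 207 lower), 23 of them by at least 2-fold. DESeq2 called 142 genes, and limma on log2(TPM + 1) 21 higher and 67 lower, and edgeR 230 without control replicate 1, 252 without slippage replicate 2 and 217 without slippage replicate 3.

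Among the lists, NF-kB targets, keratinocyte, integrin and immediate early genes moved downward in slippage-derived HCC1806 and mitotic genes upward, and these 5 held with an estimated correlation. In the mitosis list, 7 of 46 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 6.71e-05, kept at 0.0143). An example was cyclin B1 (CCNB1) at 0.24 ± 0.049. The CCNB1 call was lost on log2(TPM + 1) (adjusted p = 0.125). NF-kB targets and inflammatory cytokines fell, as 0 of 19 rose and 5 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.000190, kept at 0.0259), MMP1 and PLAU among them. Basal and squamous keratinocyte genes again went both ways, and 3 of 30 rose and 8 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.00253, kept at 0.0330). LAMB3 (-0.50 ± 0.051) and KRT14 (-0.63 ± 0.064) fell and KRT13 rose (0.46 ± 0.046). For integrins and matrix adhesion, 1 of 28 rose and 6 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.00236, kept at 0.0359). Members included the hyaluronan receptor CD44 (-0.26 ± 0.033). Immediate early genes shifted downward, where 0 of 21 rose and 7 fell (0 and 8 adjusted over the list alone; camera adjusted p = 6.88e-05, kept at 0.0259). An example was the ERK phosphatase DUSP6 at -0.51 ± 0.081. The DUSP6 call was lost on log2(TPM + 1) (adjusted p = 0.0690). The oxidative phosphorylation list moved upward, with NDUFV1 of complex I at 0.39 ± 0.068, and 11 of 72 rose and 0 fell (18 and 5 adjusted over the list alone; camera adjusted p = 0.00405, lost at adjusted p = 0.325 with an estimated correlation). Of the cytosolic ribosomal proteins, 8 of 76 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 7.77e-05, lost at adjusted p = 0.639 with an estimated correlation). For this list fry gave an adjusted p of 0.138. In the HCC1806 identity list of basal epithelial genes, 1 of 16 rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0292, lost at adjusted p = 0.110 with an estimated correlation), a call lost without control replicate 3 or slippage replicate 3 (adjusted p from 0.0947 to 0.0994).

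HCC1806 cells derived by cytokinesis failure had lower TNFAIP3, EGR1 and KRT14 and higher METTL7A, SNCG and BCAM transcripts than control. TNFAIP3, the NF-kB feedback inhibitor A20 (chromosome 6, 137866349 to 137883312 on GRCh38), fell by 2.37 ± 0.21. Its level was 3.97 ± 0.995 CPM in the doubled cells and 20.4 ± 2.62 CPM in the controls. KRT14, the basal keratin (chromosome 17, 41582279 to 41586895 on GRCh38), fell by 1.80 ± 0.072. Its level was 45.1 ± 4.93 CPM in the doubled cells and 157 ± 6.74 CPM in the controls. Lower transcripts included EGR1 (-2.67 ± 0.33), DHRS9 (-2.67 ± 0.22), the protease inhibitor SERPINB2 (-2.44 ± 0.15), MMP1 (-2.26 ± 0.089), PTGS2 (-2.18 ± 0.20) and G0S2 (-2.14 ± 0.19). METTL7A rose by 2.25 ± 0.24, SNCG by 1.46 ± 0.10, BCAM by 1.46 ± 0.16, APOBEC3B by 0.94 ± 0.25 and AGR2 by 0.73 ± 0.070. The largest adjusted p among these genes was 0.00346. CDKN1A fell by 1.18 ± 0.11, MYC by 1.05 ± 0.073 and CCNE1 by 0.44 ± 0.088. KIF18A (0.13 ± 0.085), PLK4, LATS2 and KIFC1 were not called. edgeR called 1950 of 11467 genes (960 higher and 990 lower), 178 of them by at least 2-fold, the most of the HCC1806 populations. DESeq2 called 975 genes, and limma on log2(TPM + 1) 853 higher and 453 lower.

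Immediate early genes and NF-kB targets made up the deepest shifts among the lists. Of the immediate early genes, 1 of 21 rose and 13 fell (1 and 14 adjusted over the list alone; camera adjusted p = 1.88e-10, kept at 0.00341), with a median of -0.54; DUSP6 (-1.61 ± 0.092), the AP-1 subunit FOSL1 (-1.12 ± 0.081) and IER3 (-0.88 ± 0.053) fell. Among NF-kB targets and inflammatory cytokines, 1 of 19 rose and 11 fell (2 and 11 adjusted over the list alone; camera adjusted p = 1.26e-06, kept at 0.00454), with a median of -0.85. Basal and squamous keratinocyte genes were lower on balance, and 4 of 30 rose and 12 fell (6 and 16 adjusted over the list alone; camera adjusted p = 3.42e-05, kept at 0.00640). KRT6A (-1.36 ± 0.056) and LAMB3 (-1.06 ± 0.052) fell. Integrins and matrix adhesion genes shifted downward, where 4 of 28 rose and 8 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.0268, lost at adjusted p = 0.0995 with an estimated correlation), the collagen receptor subunit ITGA2 (-1.17 ± 0.084) and CD44 (-0.52 ± 0.033) among the lower ones. Mitotic genes shifted upward, where 22 of 46 rose and 1 fell (28 and 1 adjusted over the list alone; camera adjusted p = 1.26e-06, kept at 0.00341). Members included CCNB1 (0.33 ± 0.048) and the kinetochore protein NDC80 (0.33 ± 0.064). Drug metabolism genes were lower, as 2 of 24 rose and 8 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.000551, kept at 0.0166). The near-identical aldo-keto reductases AKR1C1 (-1.76 ± 0.16), AKR1C2 (-1.07 ± 0.048) and AKR1C3 (-1.25 ± 0.12), whose reads can be shared, fell but are uncertain. Upward went epithelial genes (8 rose and 1 fell of 36, 9 and 1 adjusted over the list alone; ELF3 at 1.01 ± 0.095 and the keratin KRT19 at 0.38 ± 0.033) and oxidative phosphorylation (25 and 1 of 72, 28 and 4; NDUFV1 at 0.41 ± 0.067). For them the camera adjusted p, from 9.26e-05 to 0.0367, became adjusted p from 0.0995 to 0.161 with an estimated correlation. Heat shock and protein folding genes moved downward, where 2 of 26 rose and 12 fell (2 and 15 adjusted over the list alone; camera adjusted p = 0.0147, lost at adjusted p = 0.408 with an estimated correlation). Epithelial genes lost their call without control replicate 1 or cytokinesis replicate 1 (adjusted p from 0.0591 to 0.0597). Heat shock genes lost it without control replicate 2 or cytokinesis replicate 1 (adjusted p from 0.0597 to 0.0660). Integrins lost it without control replicate 1 or cytokinesis replicate 3 (adjusted p from 0.0511 to 0.0594).

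All 3 doubled HCC1806 populations shared 148 called genes with the same direction, 78 higher and 70 lower. SNCG and BCAM were among the higher genes and CDKN1A, DHRS9, G0S2 and KRT14 among the lower ones. Independent lists of these sizes would share 1.77 genes, and 20 simulations of unchanged groups against the same controls gave at most 0, but these had few calls to share and do not test the overlap of real calls. Genes called in the same and opposite directions numbered 167 and 17 in fusion and slippage. They numbered 438 and 73 in fusion and cytokinesis and 295 and 1 in slippage and cytokinesis. Covariances of log2 fold changes, in this order, were 0.0419, 0.0486 and 0.0630 against simulated 0.0361, 0.0375 and 0.0379. Correlations across genes were 0.41, 0.37 and 0.56 against 0.49, 0.51 and 0.52. How much of the sharing comes from the shared controls is open, as 3 libraries could not be split. The shared count was 90 and 95 without control replicates 1 and 2 and 81 without slippage replicate 3. In the mean of the 3 doubled populations against control, edgeR called 1111 genes (512 higher and 599 lower), 517 with DESeq2, 499 on log2(TPM + 1) and 721 without control replicate 1. The desaturase SCD rose by 0.49 ± 0.080. Cytidine deaminase CDA (-0.43 ± 0.076), the activin antagonist FST (-0.40 ± 0.068), the complement regulator CD55 (-0.45 ± 0.051), F3 (-0.38 ± 0.029) and CYP1B1 (-0.45 ± 0.045) fell, with adjusted p of at most 1.26e-05. Among the lists, mitosis moved upward (15 rose and 0 fell of 46) and NF-kB targets (1 and 8 of 19), keratinocyte genes (3 and 11 of 30), integrins (1 and 8 of 28), immediate early genes (1 and 11 of 21) and drug metabolism (1 and 6 of 24) downward, with camera adjusted p of at most 0.00100, and at most 0.0193 with an estimated correlation. Upward went also oxidative phosphorylation (27 rose and 0 fell of 72, 33 and 1 adjusted over the list alone) and ribosomal proteins (35 and 0 of 76, 45 and 1). Their camera adjusted p, from 1.14e-08 to 1.16e-07, became adjusted p from 0.0696 to 0.480 with an estimated correlation.

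The routes were also compared with each other in HCC1806, in tests of gene lists added after the data had been seen, where rose and fell mean higher and lower in the first-named population. Fusion against cytokinesis failure separated most genes, 2055 (1028 higher and 1027 lower in fusion), with immediate early genes and NF-kB targets higher and epithelial genes lower in fusion. DUSP6 was higher by 1.53 ± 0.094, IER3 by 0.80 ± 0.053 and FOSL1 by 0.89 ± 0.085, while CLDN1 (-0.96 ± 0.069) and KRT19 (-0.20 ± 0.033) were lower. For immediate early genes in this pair, 10 of 21 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 7.28e-06, kept at 0.0197). For NF-kB targets, 8 of 19 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.000106, kept at 0.0197). For epithelial genes, 3 of 36 rose and 17 fell (4 and 19 adjusted over the list alone; camera adjusted p = 0.000563, kept at 0.0197). Slippage against cytokinesis failure gave 780 genes (468 higher and 312 lower in slippage), again with DUSP6 (1.10 ± 0.10), FOSL1 (0.84 ± 0.085), IER3 (0.60 ± 0.054) and LAMB3 (0.56 ± 0.054) higher and KRT19 lower (-0.29 ± 0.033). Immediate early genes were higher in slippage as a list, where 9 of 21 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 2.64e-09, kept at 0.00870). Fusion against slippage gave 1058 genes (482 higher and 576 lower in fusion), with THBS1 lower at -0.46 ± 0.045. DESeq2 called 1096, 298 and 528 genes in the 3 pairs in this order, and log2(TPM + 1) gave 328 higher and 1168 lower, 91 and 281, and 196 and 311. Slippage against cytokinesis failure had 476 without slippage replicate 2 and 421 without cytokinesis replicate 1.

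Fusion-derived MDA-MB-231 cells had more called genes than the other MDA-MB-231 populations, with MMP1 and CCND2 higher and COCH and LGR5 lower than control. MMP1, an interstitial collagenase (chromosome 11, 102789919 to 102798160 on GRCh38), rose by 3.84 ± 0.30. Its level was 19.8 ± 1.51 CPM in the fused cells and 1.36 ± 0.208 CPM in the controls. Cyclin D2 (CCND2, chromosome 12, 4273762 to 4305353 on GRCh38), a partner of CDK4 and CDK6, rose by 2.19 ± 0.23. Its level was 18.6 ± 2.71 CPM in the fused cells and 4.09 ± 0.803 CPM in the controls. The membrane protein TMEM154 (2.53 ± 0.28), tenascin-C (TNC, 1.31 ± 0.24) and the adhesion receptor GPR56 (0.69 ± 0.11) rose. Cochlin (COCH, -3.36 ± 0.46), the Wnt co-receptor LGR5 (-3.10 ± 0.47), filaggrin (FLG, -2.34 ± 0.18) and the complement protein C4BPB (-1.13 ± 0.11) fell. The largest adjusted p among these genes was 9.49e-05. CCNE1 fell by 0.65 ± 0.16. KIF18A rose by 0.31 ± 0.10. The KIF18A call was lost without control replicate 1, 2 or 3 or fusion replicate 2 or 3 (adjusted p from 0.0503 to 0.126), with DESeq2 (adjusted p = 0.116) and on log2(TPM + 1) (adjusted p = 0.319). PLK4, the kinase of centriole duplication, rose by 0.55 ± 0.15. The PLK4 call was lost without fusion replicate 2 (adjusted p = 0.0564) and with DESeq2 (adjusted p = 0.0520). CDKN1A (0.080 ± 0.072), MYC, LATS2 and KIFC1 were not called. edgeR called 1993 of 11424 genes (1067 higher and 926 lower), 213 of them by at least 2-fold. DESeq2 called 1197 genes, and limma on log2(TPM + 1) 312 higher and 1394 lower, where the median of all genes lay at -0.11 (-0.12 on log2(TPM + 0.1)).

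Stress-response, sterol and TGF-beta lists moved in fusion-derived MDA-MB-231. The unfolded protein response and ATF4 targets rose on balance, and 14 of 40 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.00211, kept at 0.0462). Examples were asparagine synthetase ASNS (0.65 ± 0.11) and DDIT4 (0.52 ± 0.087). Cholesterol biosynthesis rose, where 10 of 25 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00211, kept at 0.0462). Examples were the sterol sensor partner INSIG1 (1.06 ± 0.093) and MSMO1 (0.64 ± 0.12). Targets of TGF-beta fell, as 1 of 24 rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00128, kept at 0.0462). ID1 (-0.74 ± 0.052), ID3 (-0.88 ± 0.099) and the basement membrane collagen COL4A1 (-1.19 ± 0.16) fell. Epithelial genes fell, where 1 of 24 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00366, kept at 0.0462). Examples were the keratins KRT7 (-0.56 ± 0.055) and KRT8 (-0.34 ± 0.064) and MAL2 (-0.77 ± 0.12). Among mesenchymal genes, 2 of 22 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.0362, lost at adjusted p = 0.110 with an estimated correlation). An example was FN1 at -0.74 ± 0.080. Upward went also hypoxia targets (12 rose and 1 fell of 28, 13 and 1 adjusted over the list alone; NDRG1 at 1.11 ± 0.067 and VEGFA at 0.49 ± 0.071), glycolysis (6 and 0 of 19, 8 and 0; PGK1 at 0.71 ± 0.054 and ENO1 at 0.55 ± 0.045), immediate early genes (7 and 0 of 21, 8 and 0; DUSP5 at 0.79 ± 0.093 and JUN at 0.39 ± 0.069), cytosolic ribosomal proteins (41 and 0 of 76, 50 and 0; RPS4X at 0.53 ± 0.043), oxidative phosphorylation (11 and 3 of 72, 13 and 3) and autophagy (3 and 0 of 30, 3 and 0). The camera adjusted p of these, from 8.13e-11 to 0.0362, became adjusted p from 0.0641 to 0.204 with an estimated correlation. On log2(TPM + 1) the medians of autophagy, glycolysis and oxidative phosphorylation lay below 0, though above that of all genes at -0.11. Mesenchymal genes lost their call without control replicate 1 or fusion replicate 3 (adjusted p from 0.0787 to 0.0814). Autophagy lost it without control replicate 1 or 3 or fusion replicate 1 (adjusted p from 0.0535 to 0.0634). Oxidative phosphorylation lost it without control replicate 1 or fusion replicate 1 (adjusted p from 0.0535 to 0.0684).

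Slippage-derived MDA-MB-231 cells had higher HLA-DRA, MMP1 and TGFBI and lower FLG and C4BPB transcripts than control. HLA-DRA, the MHC class II alpha chain (chromosome 6, 32439887 to 32445046 on GRCh38), rose by 1.91 ± 0.29. Its level was 11.4 ± 2.65 CPM in the slippage cells and 2.97 ± 0.759 CPM in the controls. TMEM154 (2.09 ± 0.30), MMP1 (2.09 ± 0.38), the protease inhibitor alpha-1-antitrypsin SERPINA1 (1.72 ± 0.23), the TGF-beta-induced matrix protein TGFBI (1.05 ± 0.11) and GPR56 (1.02 ± 0.11) rose. Filaggrin (FLG, chromosome 1, 152302165 to 152325239 on GRCh38) fell by 1.38 ± 0.15. Its level was 12 ± 0.953 CPM in the slippage cells and 31.5 ± 2.64 CPM in the controls. C4BPB (-1.21 ± 0.11), the inhibin subunit INHBB (-1.16 ± 0.13) and MAL2 (-0.79 ± 0.11) fell. The largest adjusted p among these genes was 0.000273. CDKN1A rose by 0.63 ± 0.068 (adjusted p = 1.44e-08). CCND2 rose by 0.98 ± 0.27. The CCND2 call was lost without control replicate 1 or 3 or slippage replicate 1 or 3 (adjusted p from 0.0520 to 0.0982), on log2(TPM + 1) (adjusted p = 0.141) and without slippage replicate 3 and cytokinesis replicate 1 together (adjusted p = 0.0654). KIF18A (0.098 ± 0.10), PLK4, LATS2, MYC, CCNE1 and KIFC1 were not called. edgeR called 706 of 11424 genes (373 higher and 333 lower), 42 of them by at least 2-fold. DESeq2 called 343 genes and limma on log2(TPM + 1) 93 higher and 76 lower, and edgeR 398 without control replicate 1, 370 without control replicate 2, 409 without control replicate 3, 442 without slippage replicate 2 and 456 without slippage replicate 3. Without both of the noisier libraries, an alternative chosen after seeing the data, the count was 726.

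Interferon, antigen presentation and NF-kB lists rose together in slippage-derived MDA-MB-231. Of the interferon-stimulated genes, 9 of 46 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 8.29e-05, kept at 0.0338). IFI27 rose by 0.53 ± 0.11, while BST2 (tetherin), also an interferon target, fell by 0.67 ± 0.093. For MHC class I antigen presentation, 7 of 20 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.000258, kept at 0.0195). Examples were B2M (0.54 ± 0.082) and HLA-B (0.58 ± 0.052), whose reads can be shared with related genes. Among NF-kB targets, 4 of 21 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 8.29e-05, kept at 0.0195). An example was the adhesion receptor ICAM1 at 0.79 ± 0.16. Integrins and matrix adhesion genes rose, as 10 of 27 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 8.38e-06, kept at 0.0162). An example was FN1 at 0.59 ± 0.069, which is also in the mesenchymal list. Mesenchymal genes rose, where 7 of 22 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00331, kept at 0.0312), S100A4 (0.48 ± 0.043) among them. The MDA-MB-231 identity list went with them, as 6 of 15 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00159, kept at 0.0296). In hypoxia targets, 9 of 28 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.77e-06, kept at 0.0195). Examples were NDRG1 (0.58 ± 0.069) and VEGFA (0.44 ± 0.070). Lysosomal genes rose, where 8 of 41 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.96e-05, kept at 0.0195). An example was cathepsin B (CTSB) at 0.35 ± 0.052. Summed immune cell markers, mostly the lysosomal CD68, rose from 79.6 ± 4.31 to 117 ± 1.22 CPM beside them. Downward went heat shock and protein folding genes (0 rose and 10 fell of 26, 0 and 14 adjusted over the list alone; HSPD1 at -0.31 ± 0.046) and Hippo targets (2 and 6 of 28, 3 and 8; CTGF at -0.36 ± 0.059, ANKRD1 at -0.33 ± 0.050 and F3 at -0.44 ± 0.058). For them the camera adjusted p, from 1.77e-06 to 0.00342, became adjusted p from 0.0870 to 0.111 with an estimated correlation. Upward went keratinocyte genes (4 rose and 0 fell of 8, 4 and 0 adjusted over the list alone), cholesterol biosynthesis (4 and 1 of 25, 4 and 1), autophagy (1 and 0 of 30, 4 and 0) and immediate early genes (1 and 0 of 21, 2 and 0). Their camera adjusted p, from 0.000125 to 0.0309, became adjusted p from 0.0508 to 0.113 with an estimated correlation. Cholesterol biosynthesis lost its call without control replicate 1 or 2 or slippage replicate 3 (adjusted p from 0.0773 to 0.0916). Autophagy lost it without slippage replicate 3 (adjusted p = 0.0785). Both calls were lost without both noisier libraries (adjusted p = 0.0647 and 0.0790).

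MDA-MB-231 cells derived by cytokinesis failure had lower interferon-stimulated genes and higher integrins than control. IFIT3, an interferon-induced antiviral protein (chromosome 10, 89327997 to 89340968 on GRCh38), fell by 0.73 ± 0.061. Its level was 165 ± 10.7 CPM in the doubled cells and 274 ± 5.17 CPM in the controls. PAPPA, a metalloproteinase that releases insulin-like growth factors (chromosome 9, 116153791 to 116402321 on GRCh38), rose by 1.27 ± 0.088. Its level was 112 ± 10.7 CPM in the doubled cells and 46.0 ± 2.52 CPM in the controls. TMEM154 (1.80 ± 0.31), MMP1 (1.71 ± 0.40) and GPR56 (1.01 ± 0.11) rose, while the acute phase protein SAA1 (-1.87 ± 0.31), C4BPB (-1.50 ± 0.11), the actin-binding AIF1L (-1.39 ± 0.24), FLG (-1.15 ± 0.15) and MAL2 (-1.02 ± 0.12) fell. The largest adjusted p among these genes was 0.00627. CDKN1A rose by 0.78 ± 0.067 (adjusted p = 4.00e-11). CCND2 rose by 1.29 ± 0.26. The CCND2 call was lost on log2(TPM + 1) (adjusted p = 0.0529). KIF18A (0.096 ± 0.11), PLK4, LATS2, MYC, CCNE1 and KIFC1 were not called. edgeR called 530 of 11424 genes (262 higher and 268 lower), 45 of them by at least 2-fold. DESeq2 called 302 genes and limma on log2(TPM + 1) 86 higher and 92 lower, and edgeR 318 without control replicate 1, 319 without control replicate 2, 346 without control replicate 3 and 353 without cytokinesis replicate 2. Without both noisier libraries the count was 677.

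Interferon-stimulated genes fell as a list in this population, where 0 of 46 rose and 13 fell (1 and 23 adjusted over the list alone; camera adjusted p = 1.11e-11, kept at 0.00621). Examples were IFIT1 (-0.78 ± 0.089), IFIT2 (-0.76 ± 0.090) and BST2 (-0.76 ± 0.095). Integrins and matrix adhesion genes rose, as 6 of 27 rose and 0 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.15e-06, kept at 0.00621). Examples were FN1 (0.80 ± 0.069) and ITGA2 (0.31 ± 0.049). Upward went mesenchymal genes (4 rose and 0 fell of 22, 5 and 0 adjusted over the list alone), the MDA-MB-231 identity list (4 and 1 of 15, 7 and 1) and hypoxia targets (6 and 0 of 28, 7 and 2; VEGFA at 0.40 ± 0.071). The camera adjusted p of these, from 0.00297 to 0.0358, became adjusted p from 0.123 to 0.15 with an estimated correlation. Downward went Hippo targets (2 rose and 6 fell of 28, 3 and 9 adjusted over the list alone; ANKRD1 at -0.82 ± 0.051, CTGF at -0.44 ± 0.059, CYR61 at -0.38 ± 0.050 and F3 at -0.51 ± 0.059) and heat shock genes (0 and 2 of 26, 1 and 8). For them the camera adjusted p, from 0.000732 to 0.00166, became adjusted p from 0.15 to 0.260 with an estimated correlation. The call of the mesenchymal list was lost without control replicate 2 or cytokinesis replicate 2 or 3 (adjusted p from 0.0557 to 0.0980). Across the 6 comparisons with control, camera called 0 of 39 tests (unadjusted 3; fry called 13) of the lists of DNA replication and origin licensing, centrosome and centriole, homologous recombination and Fanconi repair, fatty acid synthesis, proteasome, cytoskeleton and cell contraction, or, in HCC1806, cancer-testis antigens. Mitochondrially encoded mRNAs had 0 of 13 members in the tables. CDKN2A had 0 counts in all 24 libraries, and CCND2 at most 2 counts in any HCC1806 library.

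**Figure D2:**
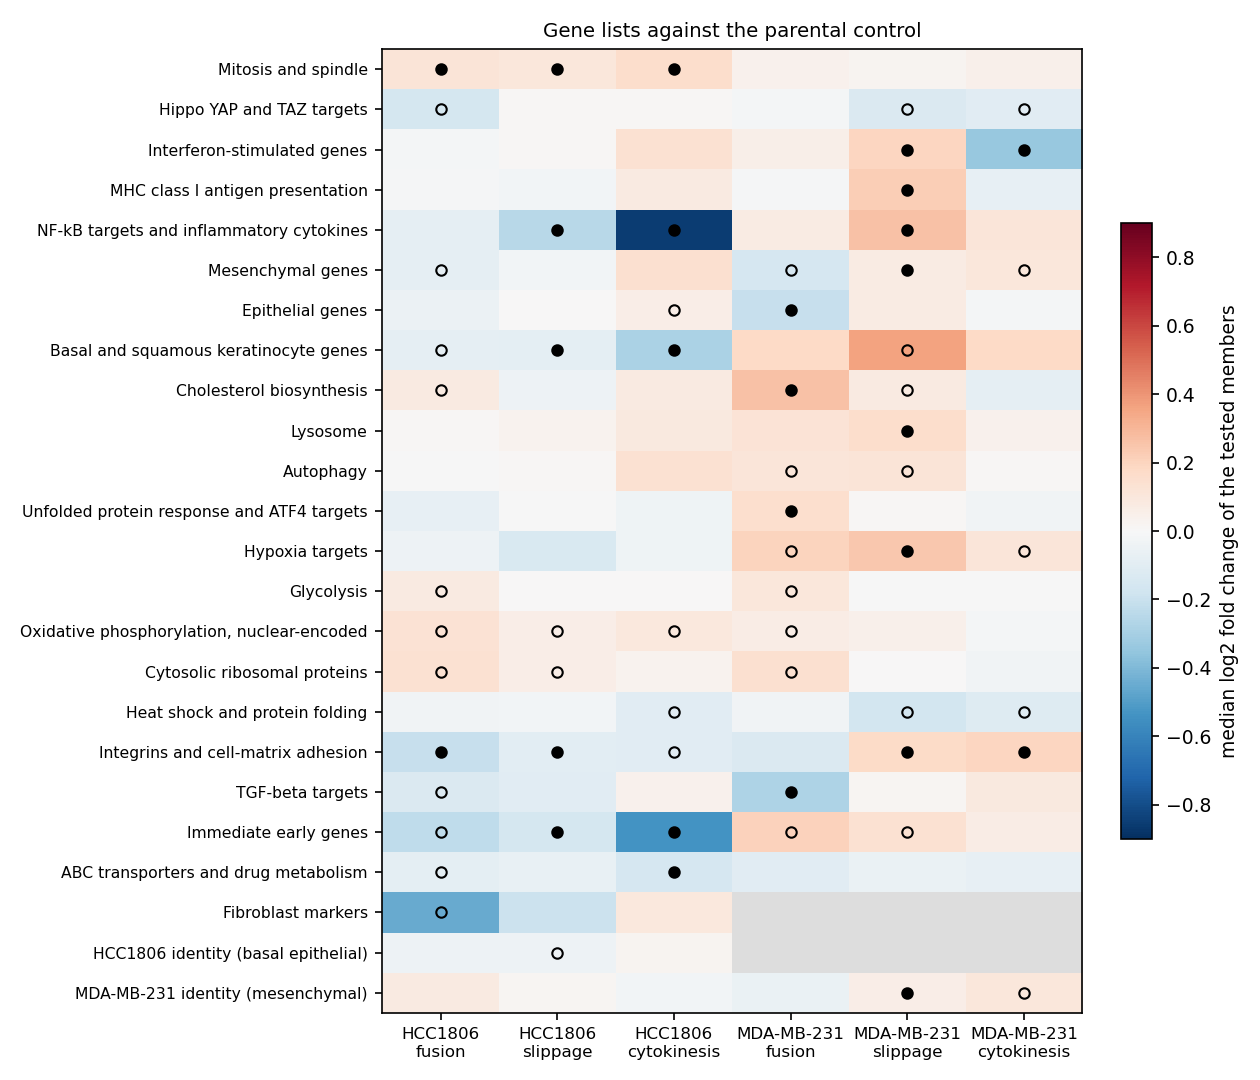
Median log2 fold change (colour) of each gene list called in any of the 6 comparisons with control (columns; grey, under 5 members tested); filled markers show lists that camera called with both the preset and an estimated correlation, open markers with the preset alone, as for immediate early genes after cytokinesis failure in HCC1806 at -0.54 (filled).

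In MDA-MB-231, 85 genes were called with the same direction in all 3 doubled populations, 53 higher and 32 lower. MMP1, TMEM154, GPR56, VEGFA and CD68 were among the higher genes, and FLG, C4BPB, MAL2 and F3 among the lower ones. Independent lists would share 1.43 genes, and simulations, with few calls likewise, gave at most 1. Same and opposite calls numbered 262 and 46 in fusion and slippage. They numbered 126 and 97 in fusion and cytokinesis and 221 and 5 in slippage and cytokinesis. Covariances in this order were 0.0487, 0.0266 and 0.0547 against simulated 0.0424, 0.0442 and 0.0444. For fusion and cytokinesis the covariance lay below the simulated one. Correlations across genes, which are not independent replicates, were 0.37, 0.20 and 0.53 against 0.50, 0.51 and 0.50. How much of the sharing comes from the 3 shared controls is open, as they could not be split. The shared count was 45 without control replicate 1 and 51 without control replicate 2. The mean of the 3 doubled populations against control gave 692 genes (350 higher and 342 lower), 348 with DESeq2, 81 higher and 148 lower on log2(TPM + 1). It gave 283 without control replicate 1, 297 without control replicate 2 and 342 without control replicate 3. SCD rose by 0.55 ± 0.061, while AIF1L (-1.12 ± 0.18), FST (-0.68 ± 0.072), CD55 (-0.39 ± 0.049), F3 (-0.54 ± 0.047) and CYP1B1 (-0.36 ± 0.049) fell, with adjusted p of at most 3.06e-05. camera called 11 lists in this mean, and fry 20, but with an estimated correlation no list of these had an adjusted p under 0.0726. Hypoxia targets led, where 7 of 28 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 1.63e-06, lost at adjusted p = 0.0726 with an estimated correlation). Immediate early genes, lysosome, the MDA-MB-231 identity list, NF-kB targets, integrins, keratinocyte genes and ribosomal proteins also moved upward, with adjusted p of at most 0.0130, and heat shock, Hippo targets and drug metabolism downward, with adjusted p of at most 0.0419. Lost calls were Hippo targets without control 1 or 3, fusion 3, slippage 2, cytokinesis 2 or 3 (adjusted p from 0.0555 to 0.0893); ribosomal proteins without control replicate 1 (adjusted p = 0.0793); drug metabolism without control 1 or 3, fusion 3, slippage 2, cytokinesis 1 (adjusted p from 0.0586 to 0.102), and the ribosomal median turned below 0 on log2(TPM + 1). Keratinocyte genes (adjusted p = 0.0563) and drug metabolism (adjusted p = 0.10) were lost without both noisier libraries.

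Between routes in MDA-MB-231, slippage and cytokinesis failure differed most in interferon-stimulated genes. Of these, 22 of 46 rose and 0 fell (31 and 1 adjusted over the list alone; camera adjusted p = 1.57e-25, kept at 0.000793), with a median of 0.48 in favour of slippage; OASL (1.21 ± 0.14) and the helicase DDX60 (1.21 ± 0.14), both chosen after their values were seen, IFIT2 (1.07 ± 0.088) and IFIT3 (0.83 ± 0.061) were higher in slippage. MHC class I genes were higher as well, where 8 of 20 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 1.31e-09, kept at 0.00217). An example was HLA-B at 0.61 ± 0.052. So was cholesterol biosynthesis, where 4 of 25 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 3.96e-06, kept at 0.00760). An example was INSIG1 at 0.76 ± 0.094. This pair had 363 called genes (240 of them higher in slippage and the rest lower), 173 with DESeq2, 60 higher and 8 lower on log2(TPM + 1), 186 when only its 6 libraries were fitted, and 221 without slippage replicate 2 and 212 without cytokinesis replicate 3. Fusion against slippage gave 1953 genes (1039 higher and 914 lower in fusion), 1210 with DESeq2 and 308 higher and 1130 lower on log2(TPM + 1). FN1 (-1.33 ± 0.076), COL4A1 (-1.38 ± 0.15), HLA-B (-0.96 ± 0.054) and ID1 (-0.80 ± 0.052) were lower in fusion. TGF-beta targets were lower, where 4 of 24 rose and 10 fell (5 and 12 adjusted over the list alone; camera adjusted p = 0.000133, kept at 0.0139). So were integrins, where 2 of 27 rose and 15 fell (3 and 16 adjusted over the list alone; camera adjusted p = 3.52e-05, kept at 0.0139). Fusion against cytokinesis failure gave 2795 genes (1443 higher and 1352 lower in fusion), 1779 with DESeq2 and 586 higher and 1950 lower on log2(TPM + 1), where the median of all genes lay at -0.10. ISG15 (1.10 ± 0.11), INSIG1 (1.00 ± 0.093) and IFIT3 (0.76 ± 0.062) were higher in fusion, and FN1 (-1.54 ± 0.075) and ID1 (-1.04 ± 0.052) lower. In interferon-stimulated genes, 21 of 46 rose and 4 fell (23 and 4 adjusted over the list alone; camera adjusted p = 1.01e-05, kept at 0.0211).

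**Figure D3:**
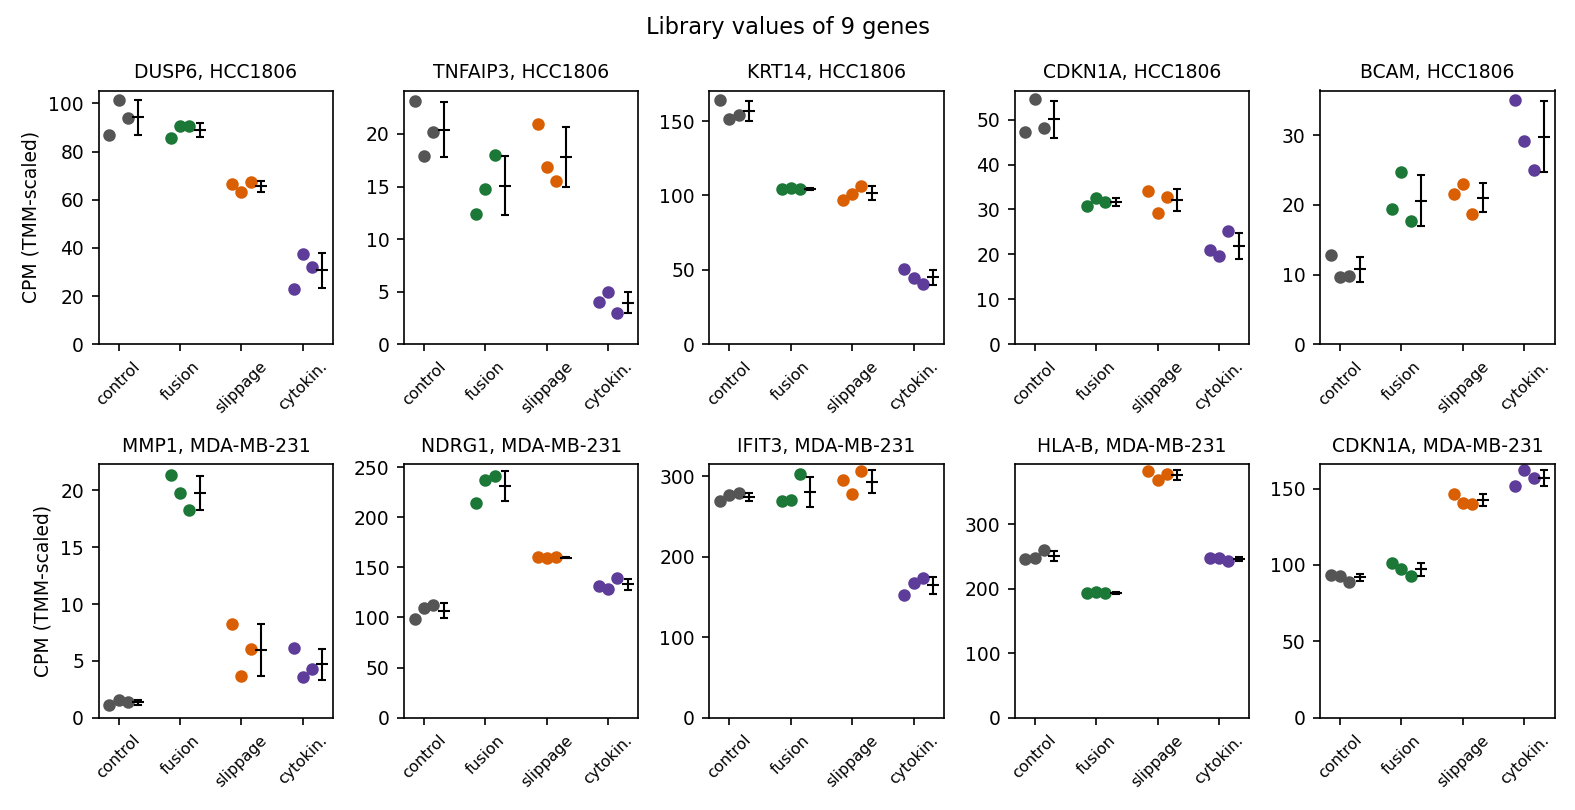
TMM-scaled CPM (y axis) of 9 genes in the 4 populations of a line (x axis); points are 3 libraries each and black marks the mean with error bars of ± SD, as for MMP1 in MDA-MB-231 with 19.8 ± 1.51 CPM in fusion.

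Fold changes against control were tested for a difference between the lines, MDA-MB-231 minus HCC1806, in a fit of all 24 libraries. CDKN1A differed in each population, by 0.74 ± 0.12 in fusion, 1.26 ± 0.12 in slippage and 1.95 ± 0.12 in cytokinesis failure, as it fell in every doubled HCC1806 population and rose in slippage and cytokinesis failure in MDA-MB-231. MMP1 differed by 3.63 ± 0.32, 3.07 ± 0.41 and 3.96 ± 0.45, and MYC by 0.52 ± 0.11, 0.48 ± 0.11 and 0.89 ± 0.12. In cytokinesis failure, the hyaluronan synthase HAS2 (3.01 ± 0.25) and PTGS2 (3.08 ± 0.67) differed, and in the mean of the populations TMEM154 (2.37 ± 0.32), SNCG (-1.42 ± 0.21) and METTL7A (-1.39 ± 0.26). The test called 1513 of 12563 genes in fusion (825 more positive in MDA-MB-231 and 688 less), 445 in slippage (236 and 209), 820 in cytokinesis failure (404 and 416) and 673 in the mean (351 and 322). DESeq2 called 1007, 284, 308 more positive and 207 less in cytokinesis failure, and 430 in the mean; log2(TPM + 1) gave 487 and 872 in fusion and 184 and 83 in slippage, and log2(TPM + 0.1) 176 and 246 in the mean. In list tests added after seeing the data, where rose means more positive in MDA-MB-231, immediate early genes differed so in the mean, where 12 of 23 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 2.07e-13, kept at 0.000223). NF-kB targets did so too, where 7 of 25 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 9.66e-08, kept at 0.000223). Integrins differed the same way, where 10 of 29 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 1.16e-06, kept at 0.000223). Mitotic genes differed towards HCC1806 (camera adjusted p = 0.0157, kept at 0.0433). The MDA-MB-231 identity list was called upward in the mean with a mean of 0.33 but a median of -0.016. Over only the genes tested in both lines, it was lost (adjusted p = 0.0542), and mitotic genes had an adjusted p of 0.0259, lost at 0.0700 with an estimated correlation. Genes called in the mean of both lines numbered 67 with the same direction, 29 higher and 38 lower, of 10369 tested in both. Independent lists would share 14.9 higher (odds ratio 2.11) and 15.5 lower (2.78). Opposite calls numbered 84, 28 higher in HCC1806 (14.7 if independent, odds ratio 2.05) and 56 lower (15.7, 4.51), and the correlation across genes was -0.069. Same and opposite calls exceeded independence, but genes are not independent replicates. SCD rose in both, and F3, FST, CD55 and CYP1B1 fell in both. The 67 became 21 with DESeq2, 42 without HCC1806 control replicate 1, and 25, 32 and 37 without MDA-MB-231 control replicates 1, 2 and 3.

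Fold changes were also summarised over 41 chromosome arms, since doubled cells can gain or lose chromosomes, with the median log2 fold change of an arm's tested genes after its name. In fusion-derived HCC1806, the short arm of chromosome 5 fell most, at -0.19, with 1 higher and 30 lower of 95 genes (camera adjusted p = 5.71e-12). Arms 20p (-0.15), 15q (-0.11), 10p (-0.099), 2p (-0.082) and 13q (-0.064) fell and 16p (0.096), 22q (0.080), 17p (0.067) and 16q (0.061) rose, with adjusted p of at most 0.0210, and all 10 were also called with an estimated correlation. In slippage-derived HCC1806, 10p (-0.14) and 4q (-0.086) fell and 19p (0.056) and 20q (0.044) rose; 19p was lost at adjusted p = 0.181 with an estimated correlation. After cytokinesis failure, 4q (-0.16) and 10p (-0.15) fell and 20q rose (0.089), with 10 higher and 71 lower of 257 genes on 4q. Arm 10p in fusion was lost without control replicate 1 or fusion replicate 2 (adjusted p from 0.0696 to 0.206). Arm 16q was lost without fusion replicate 2 (adjusted p = 0.0578) and 17p without fusion replicate 2 (adjusted p = 0.0578). In slippage, 19p was lost without control replicate 1 or 2 or slippage replicate 3 (adjusted p from 0.103 to 0.426) and 20q without control replicate 1 or 2 or slippage replicate 1 or 3 (adjusted p from 0.0841 to 0.220). In cytokinesis failure, 20q was lost without control replicate 2 (adjusted p = 0.0527). Slippage kept 2 called arms without control replicate 1, control replicate 2 or slippage replicate 3. With only genes of mean log2 CPM of at least 4, 16q in fusion (adjusted p = 0.0784) and 20q in slippage (0.0852) were lost. After a correction for GC content and transcript length, chosen after seeing the data, the calls in fusion of 10p (median -0.057, adjusted p = 0.0950), 17p (median 0.063, adjusted p = 0.0950) and 22q (median 0.065, adjusted p = 0.0950), in slippage of 19p (median 0.034, adjusted p = 0.50) and 20q (median 0.057, adjusted p = 0.0736) and in cytokinesis failure of 20q (median 0.066, adjusted p = 0.0554) were lost, and the median of 13q in fusion became -0.015.

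Fusion-derived MDA-MB-231 had 16 called arms, the most of the 6 populations. Arm 2p rose at 0.29, with 121 higher and 8 lower of 305 genes (camera adjusted p = 7.53e-17), and Xq at 0.34, with 88 higher and 17 lower of 206. Arms 4q (0.12), 5q (0.11), 7p (0.11), 8p (0.11), 10q (0.071) and 11q (0.069) rose, and 18q (-0.27), 20p (-0.21), 17p (-0.15), 2q (-0.14), 3p (-0.12), 1q (-0.11), 15q (-0.096) and 17q (-0.082) fell, with adjusted p of at most 0.0229 and at most 0.0251 with an estimated correlation. On log2(TPM + 1), where all genes lay at -0.11, arms 5q, 7p, 8p, 10q and 11q had medians below 0 but above that of all genes. The GC and length correction moved 17q to -0.050. Slippage-derived MDA-MB-231 had 8q (-0.13) and 2q (-0.098) lower and Xq (0.13) and 15q (0.083) higher. After cytokinesis failure, 5q fell at -0.16, with 2 higher and 48 lower of 420 genes (camera adjusted p = 7.80e-12), and 8q at -0.072, while 13q rose (0.074), a call lost at adjusted p = 0.133 with an estimated correlation. Arm 5q thus lay on opposite sides of control in fusion and cytokinesis failure, and the direct comparison of these populations gave 0.27 with 171 higher and 14 lower of 420 genes (adjusted p = 1.55e-13). Arm 8p in fusion was lost without fusion replicate 2 (adjusted p = 0.0582). Arm 15q in slippage was lost without control replicate 1 or 3 or slippage replicate 2 or 3 (adjusted p from 0.0736 to 0.0985), and 13q in cytokinesis failure without cytokinesis replicate 1 (adjusted p = 0.0969). Also 15q (0.0699) and 13q (0.107) were lost, by adjusted p, without both noisier libraries.

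**Figure D4:**
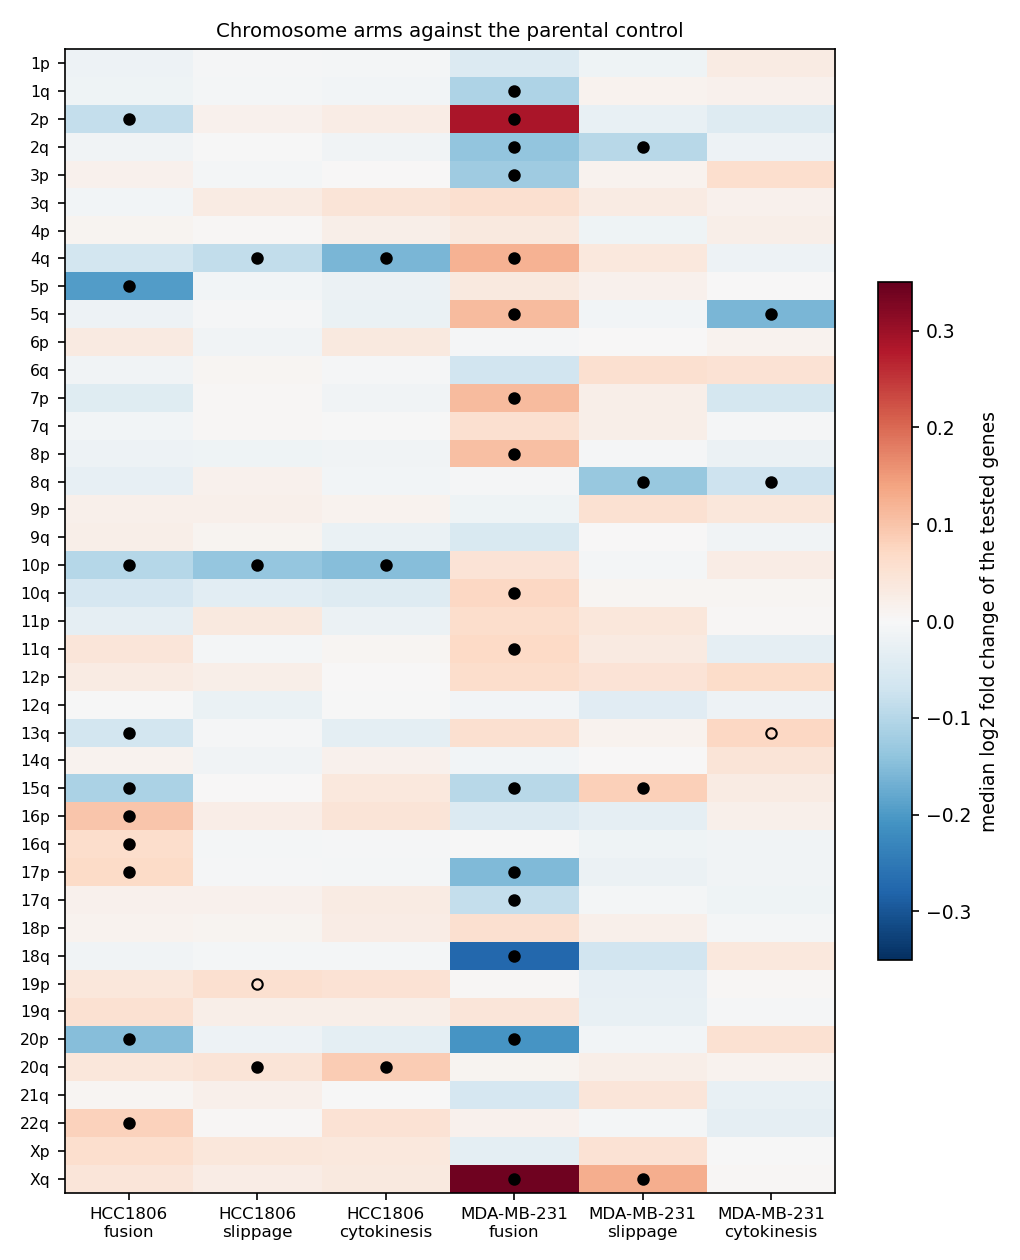
Median log2 fold change of each chromosome arm (rows) in the 6 comparisons with control (columns), with markers of camera's calls as for the lists; arm 2p in fusion-derived MDA-MB-231 stood at 0.29.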

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

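The list and arm tests in the line differences and in the pairs of doubled populations, the GC and length correction, the thinning and the test for cells of the other line were tests chosen only after the result was seen. The results given first stood out because a fold change against control differed between the lines in a direct test. With 1 population per route and line, this cannot part doubling from a population's history. Over all 12563 genes, this difference was called for 1513 in fusion, 445 in slippage, 820 in cytokinesis failure and 673 in the mean. On the log2 scale, MDA-MB-231 minus HCC1806, MMP1 differed by 3.63, 3.07, 3.96 and 3.55 in these 4 tests, CDKN1A by 0.74, 1.26, 1.95 and 1.32, and MYC by 0.52, 0.48, 0.89 and 0.63. HAS2 (3.01) and PTGS2 (3.08) differed in cytokinesis failure, and TMEM154 (2.37), SNCG (-1.42) and METTL7A (-1.39) in the mean. By camera's adjusted p, the lists that differed in fusion were keratinocyte genes (0.00690), the unfolded protein response (0.00122), hypoxia targets (0.0212), immediate early genes (5.85e-05) and fibroblast markers (0.0324) towards MDA-MB-231. In slippage they were interferon-stimulated genes (0.00185), MHC class I (0.000206), NF-kB targets (5.62e-09), mesenchymal genes (0.0120), keratinocyte genes (0.000169), cholesterol biosynthesis (0.0243), fatty acid synthesis (0.0147), lysosome (0.00716), hypoxia targets (0.000124), integrins (2.74e-08), immediate early genes (1.24e-07), HCC1806 identity (0.00914) and MDA-MB-231 identity (0.00154) towards MDA-MB-231 and mitosis (0.00784), centrosome (0.0360), Hippo targets (0.0115), ribosomal proteins (0.00584) and heat shock (0.000589) towards HCC1806. In cytokinesis failure they were NF-kB targets (5.49e-07), keratinocyte genes (5.56e-07), integrins (3.00e-07), immediate early genes (8.08e-15), HCC1806 identity (0.00908) and MDA-MB-231 identity (0.0119) towards MDA-MB-231 and mitosis (0.00680), interferon-stimulated genes (5.56e-07), epithelial genes (0.0390), cholesterol biosynthesis (0.00317), oxidative phosphorylation (4.39e-05) and ribosomal proteins (0.00590) towards HCC1806. In the mean they were NF-kB targets (9.66e-08), keratinocyte genes (5.56e-07), hypoxia targets (0.000793), integrins (1.16e-06), immediate early genes (2.07e-13), HCC1806 identity (0.0144) and MDA-MB-231 identity (0.0248) towards MDA-MB-231 and mitosis (0.0157) and oxidative phosphorylation (0.0144) towards HCC1806. With an estimated correlation the lost calls, by adjusted p, were keratinocyte genes (0.0562), hypoxia targets (0.0562) and fibroblast markers (0.0770) in fusion, centrosome (0.160), Hippo targets (0.0802), cholesterol biosynthesis (0.0802), ribosomal proteins (0.529) and heat shock (0.171) in slippage, oxidative phosphorylation (0.0520) and ribosomal proteins (0.616) in cytokinesis failure and oxidative phosphorylation (0.261) in the mean, and all others had adjusted p of at most 0.0434. On log2(TPM + 1) the median of HCC1806 identity changed sign, from 0.22 to -0.077 in cytokinesis failure and from 0.22 to -0.016 in the mean. Keratinocyte genes had 30 and 8, fibroblast markers 5 and 1 and HCC1806 identity 16 and 3 members tested in HCC1806 and MDA-MB-231, so that most of these members were hardly expressed in MDA-MB-231. Over the 10369 genes tested in both lines, 37 of 44 list calls held, while keratinocyte genes in fusion (0.168), centrosome in slippage (0.0506) and MDA-MB-231 identity in the mean (0.0542) were lost by adjusted p, and fibroblast markers and HCC1806 identity had too few members. With an estimated correlation, mitosis in the mean (0.0700), interferon-stimulated genes in slippage (0.0666) and, in cytokinesis failure, epithelial genes (0.05004) and MDA-MB-231 identity (0.0688) were lost there too.

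The arm shifts of fusion-derived MDA-MB-231 were weighed first. A bias of GC content or transcript length as the whole cause was argued against, since 16 of 16 arms stayed called after the correction, though 17q went from -0.082 to -0.050. The same correction ended 6 of 17 arm calls in HCC1806, with medians going in fusion from -0.099 to -0.057 (10p), 0.067 to 0.063 (17p) and 0.080 to 0.065 (22q), in slippage from 0.056 to 0.034 (19p) and 0.044 to 0.057 (20q) and in cytokinesis failure from 0.089 to 0.066 (20q), which neither shows nor excludes such a bias there. A single cluster of neighbouring genes was argued against in 12 arms, whose 3 equal parts by gene order had medians on the arm's side. As only signs were tested, a part of the arm stays open in all 16, and a cluster in 18q, 2q, 8p and Xq. Copy number of whole arms may still account for the 12, a hypothesis found and tested on the same data. No DNA values were analysed.

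Interferon-stimulated genes, which differed between slippage and cytokinesis failure in MDA-MB-231 by a median of 0.48, were weighed next. A single library as the cause was argued against, with a highest adjusted p of 1.44e-22 without any of the 6 libraries. Library size was argued against, with a median of 0.49 after thinning, and so was GC content or transcript length, with a median of 0.44 after the correction. The doubling route cannot be told apart from the history of a population, since each route has 1 population per line.

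The fall of immediate early genes and NF-kB targets after cytokinesis failure in HCC1806 was weighed last. Cells of the other line were argued against, since VIM implied at most 0.00918% of MDA-MB-231 cells in any cytokinesis library. A single library was argued against, with a highest adjusted p of 3.46e-06 for either list, and GC content or transcript length by a median of -0.52 for the immediate early genes after the correction, against -0.54 before. Cell density and handling at harvest, to which such genes respond, were not tested and stay open beside the doubling.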

How the results depend on the processing

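Leaving out both noisier libraries was a test chosen only after the result was seen; the other alternatives were planned. RLE factors and no filter left all 21 counts of genes within 1.5 times of those reported, as did the stricter filter for 18 (it was not run for genes shared by populations or lines) and leaving out both noisier libraries for all 16 counts they enter. Of 365 values of named genes, 50 lost their call on log2(TPM + 1) and 40 without some replicate. With DESeq2 at least 18 did, as only 319 were compared. Of 81 called lists, 49 did with an estimated correlation, 2 with fry and 19 without some replicate. Leaving out both noisier libraries ended 3 of 133 gene values, 4 of 32 lists and 2 of 7 arms. Of 40 called arms, 2 and 9 did with the correlation and without some replicate. No called value of a named gene changed direction. Totals of 2455707 to 4030297 counts limit what can be said of weakly expressed genes.

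The counts that moved beyond 1.5 times follow. With DESeq2, HCC1806 gave fusion 648, slippage 142, cytokinesis failure 975, the mean 517, fusion against slippage 528, fusion against cytokinesis failure 1096, slippage against cytokinesis failure 298 and all 3 populations 52. MDA-MB-231 gave fusion 1197, slippage 343, cytokinesis failure 302, the mean 348, fusion against slippage 1210, fusion against cytokinesis failure 1779, slippage against cytokinesis failure 173 and all 3 populations 42. The line differences gave fusion 1007, slippage 284, cytokinesis failure 515 and the mean 430. Genes shared by both lines numbered 21. With a minimum of 1 on the log2 scale, which by construction leaves fewer genes, HCC1806 gave fusion 86, slippage 23, cytokinesis failure 178, the mean 49, fusion against slippage 92, fusion against cytokinesis failure 199, slippage against cytokinesis failure 46 and all 3 populations 5. MDA-MB-231 gave fusion 213, slippage 42, cytokinesis failure 45, the mean 28, fusion against slippage 185, fusion against cytokinesis failure 281, slippage against cytokinesis failure 36 and all 3 populations 7. The line differences gave fusion 252, slippage 68, cytokinesis failure 168 and the mean 82. Genes shared by both lines numbered 0 by edgeR (0 at an unadjusted p below 0.05). On log2(TPM + 1), HCC1806 gave fusion 706, slippage 88, the mean 499, fusion against slippage 507 and slippage against cytokinesis failure 372. MDA-MB-231 gave slippage 169, cytokinesis failure 178, the mean 229 and slippage against cytokinesis failure 68. The line differences gave slippage 267. On log2(TPM + 0.1), HCC1806 gave fusion 714, slippage 84, cytokinesis failure 1267, the mean 489, fusion against slippage 505 and slippage against cytokinesis failure 349. MDA-MB-231 gave slippage 161, cytokinesis failure 175, the mean 215 and slippage against cytokinesis failure 65. The line differences gave slippage 189 and the mean 422. Fitting 6 libraries alone gave 186 for slippage against cytokinesis failure in MDA-MB-231. Of called lists, with an estimated correlation, HCC1806 gave fusion 2, slippage 5 and cytokinesis failure 5. MDA-MB-231 gave fusion 4, slippage 8, cytokinesis failure 2 and the mean 0. With fry, HCC1806 gave cytokinesis failure 20 and the mean 13. MDA-MB-231 gave fusion 21, cytokinesis failure 13 and the mean 20. Genes of mean log2 CPM of at least 4 gave 5 called arms after cytokinesis failure in MDA-MB-231. Apart from the minimum on fold change and the fits of fewer libraries, the cause was not tested.

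Leaving out each replicate in turn gave 217 to 284 genes in slippage, 721 to 1107 in the mean, 421 to 620 in slippage against cytokinesis failure and 81 to 141 in all 3 populations of HCC1806, with 2 to 4 arms in slippage. In MDA-MB-231 it gave 370 to 604 in slippage, 318 to 506 in cytokinesis failure, 283 to 792 in the mean, 212 to 302 in slippage against cytokinesis failure and 45 to 90 in all 3 populations. Genes shared by both lines numbered 25 to 77. Fewer libraries were fitted in each case, and no other cause was tested.

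The replicate numbers did not pair the libraries: of 18 pairs with the same number in each line, 0 deviated together with a correlation over 0.1 (from -0.0970 to 0.0770 in HCC1806 and from -0.191 to 0.0884 in MDA-MB-231). A replicate block in edgeR left all 35 counts within 1.5 times, with 1236 genes for HCC1806 fusion versus control and 1854 for MDA-MB-231 fusion versus control. Under the block the adjusted p was 0.0510 for mesenchymal genes and 0.0532 for glycolysis in HCC1806 fusion, 0.0555 for epithelial genes and 0.0536 for integrins after cytokinesis failure in HCC1806, 0.0668 for Hippo targets in the mean of MDA-MB-231, and 0.0722 for TNC after cytokinesis failure in MDA-MB-231. It ended no other call.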

Other observations

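No test in this part was chosen only after the result was seen. Other splits of the same libraries were fitted in the same way. A split of 6 libraries into 3 and 3 can be made in 10 ways, too few for a share under 0.05, and 1 split in each of these comparisons, the real one, gave as large a count. In HCC1806, the real split against the highest other gave 1247 against 1 genes, 13 against 3 lists and 10 against 1 arms in fusion. Slippage gave 382 against 1 genes, 8 against 2 lists and 4 against 0 arms, and cytokinesis failure 1950 against 1 genes, 9 against 2 lists and 3 against 2 arms. The pairs gave 1058 against 2 in fusion against slippage, 2055 against 0 in fusion against cytokinesis failure and 780 against 0 in slippage against cytokinesis failure. In MDA-MB-231, the real split against the highest other gave 1993 against 2 genes, 11 against 4 lists and 16 against 8 arms in fusion. Slippage gave 706 against 1 genes, 14 against 2 lists and 4 against 3 arms, and cytokinesis failure 530 against 1 genes, 7 against 3 lists and 3 against 1 arms. The pairs gave 1953 against 1 in fusion against slippage, 2795 against 0 in fusion against cytokinesis failure and 363 against 2 in slippage against cytokinesis failure.

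For the results with more splits, 100 were drawn, the real one included. Only 1 of 100 gave as large a count for the mean of the doubled populations (HCC1806 1111 against 30 genes, MDA-MB-231 692 against 12). The line differences did likewise (fusion 1513 against 48, slippage 445 against 21, cytokinesis failure 820 against 368, mean 673 against 73). This tests the grouping of libraries, not chance between populations derived once. The share was 1 of 100 for genes called alike in all 3 populations (148 against 2, 85 against 1) and both lines (67 against 0). The other splits called few genes and do not test the overlap of real calls. For the lists in the mean, 4 of 100 splits gave as many in HCC1806 (real 8, highest other 10) and 3 of 100 in MDA-MB-231 (real 11, highest other 13), shares under 0.05.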
